A study of Homo sapiens with 6 samples.

How the data were processed

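Total RNA from HEK293, an established human embryonic kidney cell line, was measured in 6 libraries, 3 labelled TRDMT1 knockdown and 3 labelled control. TRDMT1 (DNMT2) is a methyltransferase that places the mark m5C, a methylated cytosine, in the anticodon loop of certain tRNAs. Per the labels' protocols, RNA was taken up in Trizol, ribosomal RNA was depleted, the remaining RNA was treated with a bisulfite kit for RNA methylation, and libraries were made with a stranded total RNA kit. Bisulfite converts unmethylated cytosine to uracil. Whether the deposited table was made from bisulfite-treated or untreated libraries is not given in the sources used here, and neither is the aligner, the strand setting of the counting or the gene annotation.

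The deposited table held read counts per gene, which the authors had not normalized, and RPKM values, which scale each count by exonic length and library total, computed by the authors from the same counts. Per the submitters' processing notes, bcl2fastq 2.17.1.14, HTSeq 0.6.1, StringTie 1, DESeq2 1.6.3, DESeq 1.18.0 and edgeR 3.4.6 were used with genome build hg19, with no role or order stated. The deposited RPKM values equalled the count scaled by exonic length and by the library's total count, within 0.006, for 100% of values. The table's columns carried second names for the samples, and each column was tied to a sample by the second name in that sample's description. These second names read the other way round from the sample titles, so the direction of every comparison rests on titles and genotype labels that the level of TRDMT1 did not bear out. Groups are therefore called the libraries labelled knockdown and the libraries labelled control throughout. All per-sample columns were tied to a sample, and no line of the table lacked a gene name.

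Each library held between 24776040 and 40088993 counts over 57773 genes. The 95% Wilson intervals of single libraries and the floor of 3 counts for genes at 0 cover counting error only. The labels do not say that the 3 libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. Counts of every pair of libraries differed by more than sampling noise, so each library was counted once in n. This does not show that the libraries came from separate cultures. Both groups shared the estimate of spread in the fit. The coefficient of variation was 5.45% in the libraries labelled knockdown and 31.8% in those labelled control.

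Counts were tested with edgeR 4.0.16 in R 4.3.3 by the quasi-likelihood F test, with TMM normalization, the filterByExpr filter and robust estimation. The filter left 17805 genes. Fold changes are log2 values of the libraries labelled knockdown minus the libraries labelled control, given ± their standard error, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. CPM are counts scaled to the library total after TMM, in the usual unit, as mean ± SD over 3 libraries. The level of TRDMT1 was also tested with an exact two-sided permutation test on log2(RPKM + 1). The design had foreseen either counts or RPKM, and the count test was used because counts were deposited.

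Before the data were examined, 32 gene lists with 855 genes were fixed, together with the tests, the other settings to be tried and the rule for named genes. Of these lists, 30 had at least 5 tested members and were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, adjusted over the lists. An estimated correlation and fry stood beside it. The named genes were TRDMT1, then the 10 genes with the largest rise and the 10 with the largest fall among those past the threshold whose groups did not overlap, with a gene symbol and a mean of at least 5 RPKM in the higher group. To these were added the 3 members with the smallest p in the direction of the call for each called list, and every member of the RNA m5C list past the threshold. Some genes that this rule names or a list holds are not reported here. Other members are given as examples of a list's count, and were chosen after their values were seen.

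Base composition, chromosome and gene class came from GENCODE release 29, matched by gene identifier for 97.2% of the tested genes. The base composition of a gene was that of its longest transcript in that annotation. That annotation is of another genome build than the authors used, so no coordinates are given, and identifiers and exonic lengths are those of the deposited table. Base composition and length trends were removed in an added alternative by smooth terms per library (mgcv 1.9.3) used as offsets in edgeR. Further alternatives were limma-trend on log2(RPKM + 1), DESeq2 1.42.0, voom with sample quality weights, other filters and scalings, a replicate block and leaving out each library. Gene Ontology terms with 20 to 300 tested genes were tested with camera.

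The fit was tested on simulated counts for the 17805 genes of this comparison, with 200 genes changed. The simulation gave both groups the same spread per gene and held no outlying library. The real groups differed in spread, with a coefficient of variation of 5.45% in the libraries labelled knockdown and 31.8% in those labelled control. Changed genes were drawn only from genes above a minimum mean count. The fit recovered 41% of genes changed 2-fold and 95% of those changed 4-fold, and 6.21% of its calls were unchanged genes. With a simulated composition trend, the number of unchanged genes called fell from 984 to 9 after the correction, and 39% of 2-fold and 97% of 4-fold changes were recovered. That trend was linear in A content, which the correction fits. It was also stronger than the real one, with a Spearman correlation of −0.78 against −0.44 among real protein-coding genes. The simulation therefore does not show how fully the correction removes the real trend.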

Results

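Gene expression was measured by RNA sequencing in HEK293 cells, an established human embryonic kidney line, in 3 libraries labelled TRDMT1 knockdown and 3 libraries labelled control. The design asked which transcripts differ when TRDMT1, a tRNA m5C methyltransferase also called DNMT2, is depleted. The libraries labelled knockdown held 36455950, 36737468 and 40088993 counts, and the libraries labelled control 26465603, 24776040 and 26802182.

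TRDMT1 itself was not lower in the libraries labelled knockdown. TRDMT1 (ENSG00000107614, chromosome 10) had 221, 225 and 245 counts in the libraries labelled knockdown and 99, 93 and 80 counts in the libraries labelled control. Its level was 5.74 ± 0.02 CPM against 3.76 ± 0.86 CPM (SD, n = 3 each), 1.53-fold higher in the libraries labelled knockdown. Against the plain library total it was 6.06, 6.12 and 6.11 CPM in the libraries labelled knockdown, and 3.74, 3.75 and 2.99 CPM in the libraries labelled control. The 95% Wilson interval of the lowest library labelled knockdown ran from 5.31 to 6.92 CPM and that of the highest library labelled control from 3.06 to 4.60, so that the groups did not overlap.

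The log2 fold change of TRDMT1 was 0.61 ± 0.21, with an adjusted p of 0.0705 by edgeR's quasi-likelihood test, and all 3 libraries labelled knockdown lay above all 3 labelled control. The exact two-sided permutation test on log2(RPKM + 1) gave p = 0.1, the smallest that 3 against 3 libraries allow. DESeq2 called the difference (log2 fold change 0.64, adjusted p = 0.0195), and so did edgeR without control replicate 2 (0.79, adjusted p = 0.00249), over a range of adjusted p from 0.00189 to 0.202 across the model fits. TRDMT1 thus goes against the group labels, and every direction given here is between libraries as labelled.

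**Figure D1:**
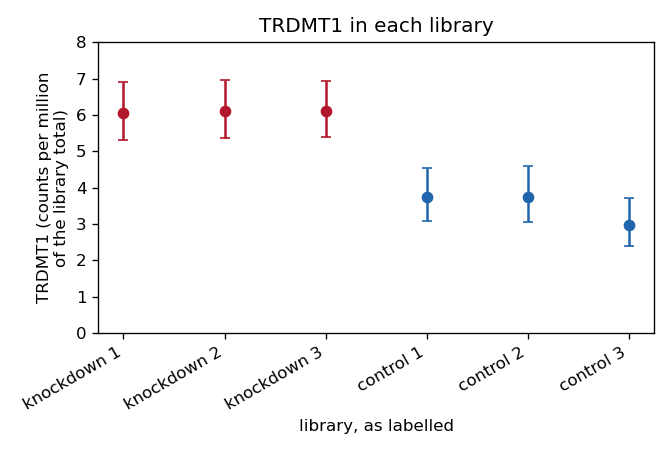
TRDMT1 in each library, in CPM of the library total (vertical axis, from 0), with 95% Wilson intervals as bars (counting error only). The 3 libraries labelled knockdown lie between 6.06 and 6.12 and the 3 labelled control between 2.99 and 3.75.

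The 6 libraries separated by label. The first principal component of log2 CPM held 61.8% of the variance and parted the libraries labelled knockdown from those labelled control, and the second held 27.6% and parted control replicate 2 from control replicates 1 and 3. Libraries labelled knockdown correlated with each other at 0.995 to 0.996 across genes, which are not independent replicates. Control replicates 1 and 3 correlated at 0.989, and control replicate 2 with these at 0.963 and 0.951. The biological coefficient of variation was 5.45% among the libraries labelled knockdown and 31.8% among those labelled control. Control replicate 2 also had 2.51% of its counts in processed pseudogenes, against 0.895% to 1.16% in the other 5 libraries. The small nucleolar RNA host transcripts GAS5 and SNHG1 stood at 457 and 292 CPM of the plain library total there, against 75.2 to 95.7 and 74.8 to 92.0 elsewhere, and its TMM factor was 0.812.

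**Figure D2:**
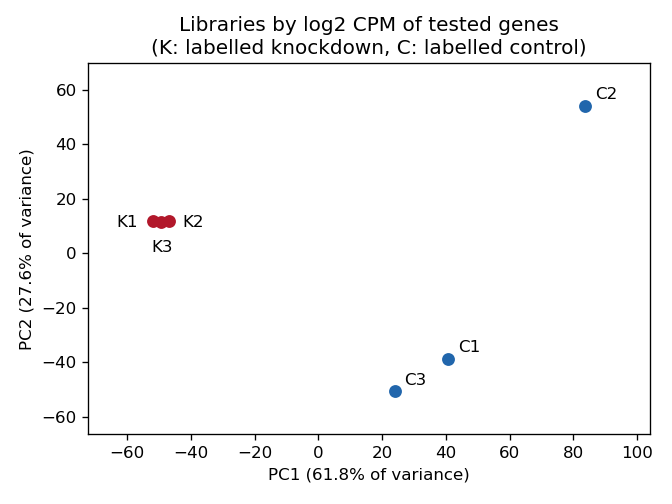
Principal components of log2 CPM over the tested genes, PC1 (61.8% of variance) on the horizontal and PC2 (27.6%) on the vertical axis. Each point is a library (K labelled knockdown, C labelled control, with its replicate number), and control replicate 2 lies apart from control replicates 1 and 3.

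Among called genes with a mean of at least 5 RPKM in the higher group and no overlap between groups, CENPE, GOLGA4, CENPF and ASPM had the largest decreases in the libraries labelled knockdown. CENPE, a kinetochore motor, stood at 4.38 ± 0.39 CPM against 75.2 ± 25.3 CPM (log2 fold change −4.10 ± 0.29, adjusted p = 0.000438, edgeR), 17.2-fold lower. CENPF, a kinetochore protein, was 14.3-fold lower (−3.84 ± 0.31), ASPM, a spindle pole protein, 12.7-fold lower (−3.67 ± 0.30), and KIF20B, a mitotic kinesin, 11.8-fold lower (−3.56 ± 0.28). The Golgi proteins GOLGA4 (−4.06 ± 0.24) and GOLGB1 (−3.31 ± 0.15) were 16.7-fold and 9.92-fold lower. TPR, of the nuclear pore basket, fell from 379 ± 44.7 to 35.1 ± 0.20 CPM (−3.43 ± 0.14, adjusted p = 0.000106). KTN1, a kinesin-binding protein of the endoplasmic reticulum (−3.46 ± 0.23), FAM111B (−3.41 ± 0.13) and the secreted protein NELL2 (−3.35 ± 0.16) completed the 10 largest decreases under this rule, whose adjusted p ran up to 0.000642. With base composition and length trends removed, a correction chosen after the data were seen, all 10 were still called, with smaller changes for CENPE (−3.00 ± 0.19), GOLGA4 (−3.02 ± 0.14), CENPF (−2.83 ± 0.19), ASPM (−2.65 ± 0.18), KIF20B (−2.32 ± 0.20), TPR (−2.60 ± 0.14), FAM111B (−2.22 ± 0.11) and GOLGB1 (−2.47 ± 0.17). KTN1 (−3.33 ± 0.12) and NELL2 (−3.46 ± 0.15) moved by less.

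Among the largest increases under the same rule, the desmosomal protein PKP3 stood at 48.4 ± 2.07 CPM in the libraries labelled knockdown against 4.95 ± 3.23 CPM in those labelled control (3.31 ± 0.43, adjusted p = 0.00342, edgeR), 9.89-fold higher. HERPUD1, a factor of protein degradation at the endoplasmic reticulum, stood at 204 ± 5.25 against 36.2 ± 20.4 CPM, 5.65-fold higher (adjusted p = 0.00692). TMEM47, a junction protein (2.56 ± 0.39), STS, the steroid sulfatase (2.42 ± 0.32), ECHDC3 (2.10 ± 0.23) and the transcription factor BHLHA15, known from secretory cells (2.03 ± 0.43), were also higher. The antisense transcript VPS9D1-AS1 (2.55 ± 0.27) is uncertain because the strand setting of the counting is not given. RN7SK (3.13 ± 0.74) and RN7SL2 (2.05 ± 0.52), structural RNAs with many near copies in the genome, and MIR635 (1.95 ± 0.37), which stood at 1.04 ± 0.15 CPM, are uncertain too. All 10 had an adjusted p of at most 0.0315, and the call of BHLHA15 ended with the trends removed (1.52 ± 0.46, adjusted p = 0.06).

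Over all 17805 genes tested, 4267 differed between the libraries as labelled, 1654 higher and 2613 lower in the libraries labelled knockdown, and 1977 of them differed by at least 2-fold (555 higher and 1422 lower). Without control replicate 2 the count rose to 9063 (4279 higher, 4784 lower) and without control replicate 3 to 5417 (2297 higher, 3120 lower), whereas leaving out 1 library labelled knockdown gave 1191 to 1315 and leaving out control replicate 1 gave 2044. On log2(RPKM + 1), where the median of all genes lay at 0.12 and not at −0.04, limma-trend called 1788 genes higher and 1232 lower.

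Genes of the ER unfolded protein response were higher as a group in the libraries labelled knockdown. Of 18 tested, 9 were higher, 0 lower and 9 not called (9 and 1 adjusted over the list alone), with a median log2 fold change of 0.66. Besides HERPUD1, the ubiquitin ligase SYVN1 (1.71 ± 0.11, adjusted p = 0.000319, edgeR), the chaperone HSPA5 (1.73, adjusted p = 0.0218), PDIA4 (1.53) and the co-chaperone DNAJC3 (0.79 ± 0.12, adjusted p = 0.00546) were higher. The list was called by camera with an adjusted p of 0.000251, and had an adjusted p of 0.767 with an estimated correlation. HERPUD1 and SYVN1 lie on chromosomes 16 and 11, whose genes were higher together (medians 0.528 and 0.305), so part of their rise may be shared with their chromosomes. Without the 6 chromosomes that shifted most, 6 members were left out. Of the 12 members left, 5 were higher and 0 lower, with a median of 0.549. Camera with the preset correlation still called them (adjusted p = 0.0047).

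Of 24 targets of ATF4 and the integrated stress response, 4 were higher and 0 lower (4 and 0 adjusted over the list alone), with a median of 0.15. These were the pseudokinase TRIB3 (1.67 ± 0.13, adjusted p = 0.000537, edgeR), SESN2 (1.10 ± 0.13), the amino acid transporter SLC7A5 (248 ± 8.02 against 87.7 ± 38.3 CPM) and the lipoprotein receptor VLDLR (0.75). Camera gave an adjusted p of 0.0103, against 0.801 with an estimated correlation, and the call ended without control replicate 3 (adjusted p = 0.441). TRIB3, SLC7A5 and VLDLR lie on chromosomes 20, 16 and 9, whose genes shifted together, and without those and chromosomes 3, 11 and 14 the list was not called (adjusted p = 0.0736, 1 of 17 higher).

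Heat shock genes were lower in the libraries labelled knockdown. Of 16 heat shock genes, 9 were lower and 0 higher (11 and 0 adjusted over the list alone), with a median of −0.82, which was −0.48 with 6 lower when composition and length trends were removed. HSPE1, a mitochondrial co-chaperonin, stood at 112 ± 7.01 against 210 ± 22.6 CPM (−0.91 ± 0.13, adjusted p = 0.00428, edgeR), and HSPB1 (−0.91 ± 0.15), HSPA8 (−1.35) and HSP90AA1 (−1.31) were lower too. HSPA1B (−4.58 ± 0.78) shares reads with its near-identical neighbour HSPA1A and is uncertain. Camera called the list with an adjusted p of 0.00119, which was 0.798 with an estimated correlation.

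Proteasome subunits were lower as a group. Of 31 tested, 13 were lower and 0 higher (13 and 0 adjusted over the list alone), with a median of −0.45 and a camera adjusted p of 8.16e-05, against 0.767 with an estimated correlation. PSMC6 (−1.93 ± 0.14, adjusted p = 0.000424, edgeR), PSMA3 (−1.52 ± 0.13) and PSMC1 (−1.22 ± 0.14) led the list. Of the 13 called members 5 lie on chromosome 14, these 3 among them, and the median over the 468 tested protein-coding genes of that chromosome was −0.50. With composition and length trends removed the proteasome median was −0.30, with 9 lower and 0 higher. Camera then gave an adjusted p of 0.000293, and 0.704 with an estimated correlation. PSMA3 then stood at −0.63 ± 0.10, PSMC6 at −1.56 ± 0.15 and PSMC1 at −1.21 ± 0.10.

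Messages for the cytosolic ribosome were lower as a group, with a median of −1.07 over 77 genes and a camera adjusted p of 9.46e-05, against 0.801 with an estimated correlation. Only 2 genes were called singly, both lower (1 adjusted over the list alone). RPS25 was among the called genes (−2.21 ± 0.64, adjusted p = 0.0463, edgeR), while RPL24 (−1.33 ± 0.42, adjusted p = 0.0574) was not called. RPS25 stood at only 0.60 ± 0.09 CPM in the libraries labelled knockdown against 2.83 ± 2.56 CPM in those labelled control, so its change is uncertain. RPL24 stood at 330.9 ± 19.06 against 834.5 ± 531.5 CPM. These genes have many processed pseudogenes with which they share reads, and the estimated correlation between them was 0.985. Control replicate 2, with the highest share of processed pseudogene counts (2.51%), moved with this list: camera gave an adjusted p of 0.00527 without it, against 4.47e-07 without control replicate 1 and 2.6e-08 without control replicate 3, and fry did not call the list (adjusted p = 0.397). Nuclear genes of oxidative phosphorylation had a median of −0.42, with 11 of 49 lower and 1 higher (16 and 1 adjusted over the list alone). COX7B (−2.19 ± 0.28, adjusted p = 0.00311, edgeR), NDUFB3 (−1.01 ± 0.17) and NDUFS5 (−0.82 ± 0.21) were lower and SDHD (0.86) was higher. Camera gave an adjusted p of 0.00119, and 0.801 with an estimated correlation. It was 0.0214 without control replicate 2, 0.00153 without control replicate 1 and 1.59e-06 without control replicate 3, and fry did not call the list (0.243).

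Mitotic genes were lower in the libraries labelled knockdown. Of 35 genes of mitosis and G2/M, 13 were lower and 0 higher (13 and 0 adjusted over the list alone), with a median of −0.31. With composition and length trends removed 6 were lower and 1 higher, with a median of −0.225. The uncorrected median of −0.31 lay inside the central 95% of 10000 random lists matched on A content and length (−0.62 to −0.13), whose median was −0.38. After CENPE and CENPF the genes called lower as fitted included the checkpoint kinase TTK (−2.84 ± 0.21, adjusted p = 0.000485, edgeR), the cyclin-dependent kinase CDK1 (−1.68 ± 0.13) and TOP2A (−1.26). Camera called the list with an adjusted p of 0.00119, which was 0.798 with an estimated correlation. Of 35 genes of DNA replication and G1/S, 2 were higher and 3 lower, with a median of 0.02 and a camera adjusted p of 0.479.

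Genes of homologous recombination were lower too, 12 of 28 against 1 higher, RAD51D (0.60), and as many adjusted over the list alone, with a median of −0.36. BRCA2 (−2.43 ± 0.27, adjusted p = 0.00197, edgeR), the nuclease partner RAD50 (−1.59 ± 0.22) and the end-resection factor RBBP8 (−1.39 ± 0.13) had the smallest p. Camera gave an adjusted p of 0.00119, and 0.71 with an estimated correlation. The call ended when trends with base composition and length were removed (adjusted p = 0.33), a correction chosen after the data were seen. The median was then −0.21, with 8 lower and 3 higher. BRCA2 (−1.43 ± 0.16), RAD50 (−1.085 ± 0.141) and RBBP8 (−0.54 ± 0.14) were still called, with smaller changes.

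**Figure D3:**
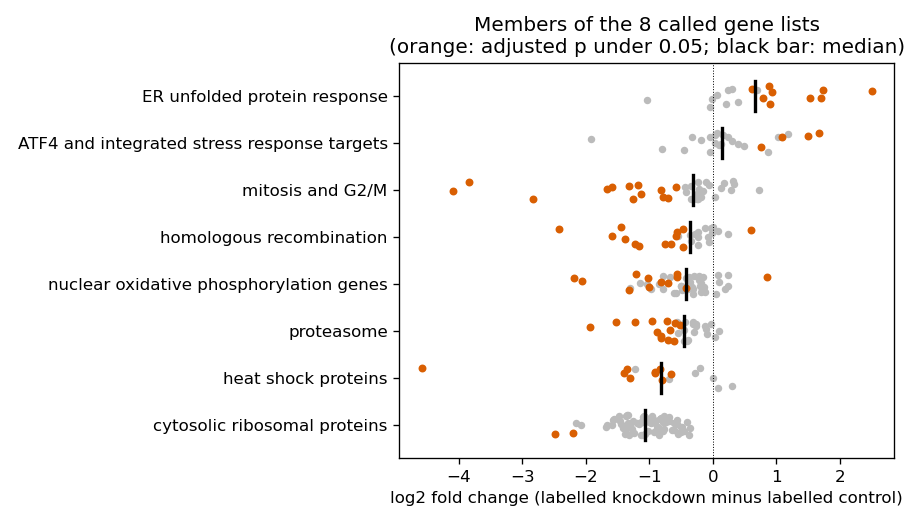
Log2 fold change (horizontal axis, libraries labelled knockdown minus libraries labelled control) of each tested member of the 8 called lists, 1 point per gene, orange where the adjusted p passed, with the median as a black bar. The ER unfolded protein response (0.66) and the ATF4 targets (0.15) lie above 0, and the medians of the other 6 lists lie between −1.07 and −0.31.

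The m5C machinery moved in no common direction. Of 17 RNA m5C writers, readers and erasers, 1 was higher, 4 were lower and 12 were not called (1 and 4 adjusted over the list alone), with a camera adjusted p of 0.933 and a median of −0.07. The DNA methyltransferase DNMT1 was higher, at 424 ± 14.7 against 270 ± 63.5 CPM (0.65 ± 0.19, adjusted p = 0.0493, edgeR). The oxidase TET2 (−0.90 ± 0.17, adjusted p = 0.0119), the tRNA methyltransferase NSUN6 (−0.62 ± 0.16), the demethylase ALKBH1 (−0.51 ± 0.14) and the m5C reader ALYREF (−0.43 ± 0.12) were lower. With composition and length trends removed only TET2 was still called (−0.81 ± 0.14, adjusted p = 0.011), while NSUN6 stood at −0.02 ± 0.20 (0.95), DNMT1 at 0.30 ± 0.11 (0.1), ALYREF at −0.41 ± 0.15 (0.102) and ALKBH1 at −0.48 ± 0.15 (0.064). NSUN2, the main m5C methyltransferase of mRNA, stood at −0.07 ± 0.13 (adjusted p = 0.742). Of 26 enzymes of tRNA modification and tRNA fragments, 1 was higher and 4 lower, among them TRMT10C (−2.18) and TRMT5 (−1.05), with a camera adjusted p of 0.242. Camera called that list lower with the GC trend removed (adjusted p = 0.0159) but not with composition and length trends removed (0.0509), where 6 were lower and 0 higher with a median of −0.31. An estimated correlation gave the list an adjusted p of 0.798 as fitted and 0.704 with composition and length trends removed.

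The remaining lists did not pass camera, and their called members are counts over all genes tested. Of 45 genes of migration, adhesion and matrix, 5 were higher, with fibronectin FN1 at 1.16, and 10 lower, with the transcription factor ZEB1 at −2.46 and the kinases ROCK1 at −2.07 and ROCK2 at −1.60 (6 and 11 adjusted over the list alone, camera adjusted p = 0.942). Of 36 genes of the nuclear pore and RNA transport, 7 were higher and 12 lower, with RANBP2 at −3.11 and THOC2 at −2.59 (8 and 14 adjusted over the list alone, adjusted p = 0.255). Of 37 splicing factors, 2 were higher and 13 lower (adjusted p = 0.134), of 29 ribosome biogenesis genes 1 and 7 (0.134), and of 30 chromatin regulators 3 and 5 (0.688). Of 23 interferon-stimulated genes, 2 were higher and 6 lower, with IFI44L at −5.49 and SAMD9 at −3.25 (adjusted p = 0.237). Of 24 immediate early genes, 6 were higher, with EGR1 at 1.56 and SPRY4 at 1.82, and 2 lower, CTGF (−0.88) and CYR61 (−0.73) (adjusted p = 0.134). Of 23 cholesterol synthesis genes, 5 were higher, with DHCR7 at 0.88, and 1 lower, IDI1 at −0.58 (adjusted p = 0.237).

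Few members were called in the other lists. Of 24 p53 targets 1 was higher, PLK3 at 0.59 (camera adjusted p = 0.255), and of 26 apoptosis and anoikis genes 1 was higher, BCL2L1, and 1 lower, BIRC2 (0.654). Of 29 glycolysis and hypoxia targets 2 were higher and 2 lower (0.736), and of 19 aminoacyl-tRNA synthetases AARS was higher and RARS lower (−0.70), with an adjusted p of 0.392. Of 16 housekeeping genes B2M, TBP and HPRT1 were lower (0.23), of 15 mitochondrially encoded genes MT-ATP8 was higher (0.168), and none of 16 replication-dependent histones was called (0.392). Without control replicate 2, camera called the histones (adjusted p = 0.000287) and mitochondrially encoded genes (0.0321) higher and ribosome biogenesis (0.0214) lower. With an estimated correlation over all 6 libraries these stood at 0.88, 0.801 and 0.798. Mitochondrially encoded genes were also called with the GC trend removed (0.0437). Of 10 abundant nuclear and small structural RNAs only RN7SK and RN7SL2 were called (0.451). Median, mean and test differed in sign for 9 lists, none of them called: m5C, migration, apoptosis, DNA replication, glycolysis, histones, and the markers of HEK293, epithelial and fibroblast identity.

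Most markers of HEK293 identity were present in all 6 libraries. Of 13 tested, SALL1 (0.77) and GATA3 (0.56) were higher in the libraries labelled knockdown and 11 were not called (camera adjusted p = 0.516), with the neurofilament NEFL at 148 to 246 CPM of the plain library total, the unit of all CPM given for markers here. Of 9 epithelial markers KRT5 was higher and KRT17 and EPCAM lower (0.563). Of 9 fibroblast markers COL1A2 and ACTA2 were higher and LUM lower (0.392). KRT5 and LUM were low in all libraries. In the libraries labelled knockdown against those labelled control, KRT5 stood at 0.354 to 0.686 against 0 to 0.113 CPM. LUM stood at 0.439 to 0.708 against 0.756 to 1.83 CPM. Blood and liver lists had too few tested members, with PTPRC at most 0.0746 and ALB at most 0.686 CPM, but the blood list's actin-binding protein LCP1 stood at 147 to 268, CORO1A at 2.02 to 7.41 and CD14 at 1.21 to 1.68 CPM. COL1A2 had 0 counts in every library labelled control and 4.19 CPM over the summed totals of the libraries labelled knockdown, at least 109-fold higher against the floor of 3 counts over the group. TACR3, a neurokinin receptor singled out after its values were seen, showed the opposite, with 0 counts in every library labelled knockdown and 5.55 CPM over the summed totals of the libraries labelled control, at least 210-fold lower. These 2 were the only genes at 0 in all 3 libraries of 1 group with a mean of at least 1 CPM, after TMM, in the other.

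Fold changes followed the base content of the transcripts. Among 13896 protein-coding genes the Spearman correlation of log2 fold change was −0.44 with A content and 0.46 with C content, across genes, which are not independent replicates. In the 1389 genes lowest in A the median was 0.26, with 268 genes higher and 40 lower, and in the 1390 genes highest in A it was −0.88, with 20 higher and 803 lower. The longest transcript of CENPE was 41.4% A and that of GOLGA4 38.4%, against 18.0% for PKP3.

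Fold changes also followed the chromosome. On chromosome 14, 186 protein-coding genes were lower and 2 higher, with a median of −0.50, and on chromosome 16, 274 were higher and 11 lower, with a median of 0.53. Medians were 0.30 on chromosome 11, 0.28 on chromosomes 9 and 20, and −0.29 on chromosomes 3 and 13. With composition and length trends removed, chromosome 13 stood at −0.11, inside the central range of 10000 random gene sets of its size (−0.16 to −0.01), and chromosome 3 at −0.26, outside it (−0.12 to −0.04). Of 23 chromosomes 13 lay outside their ranges, and chromosomes 3, 9, 11, 14, 16 and 20 lay farthest from the middle of theirs. A whole-chromosome median hid a segment of chromosome 6, where the runs of 50 or more neighbouring genes from SENP6 to PDCD2, numbers 8 to 13 of 13, had corrected medians from −0.54 to −0.15, while runs 1 to 3 had 0.08 to 0.30. HERPUD1, SLC7A5 and VPS9D1-AS1 lie on chromosome 16, PKP3 and SYVN1 on chromosome 11, and KTN1, ALKBH1 and PSMC6 on chromosome 14.

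**Figure D4:**
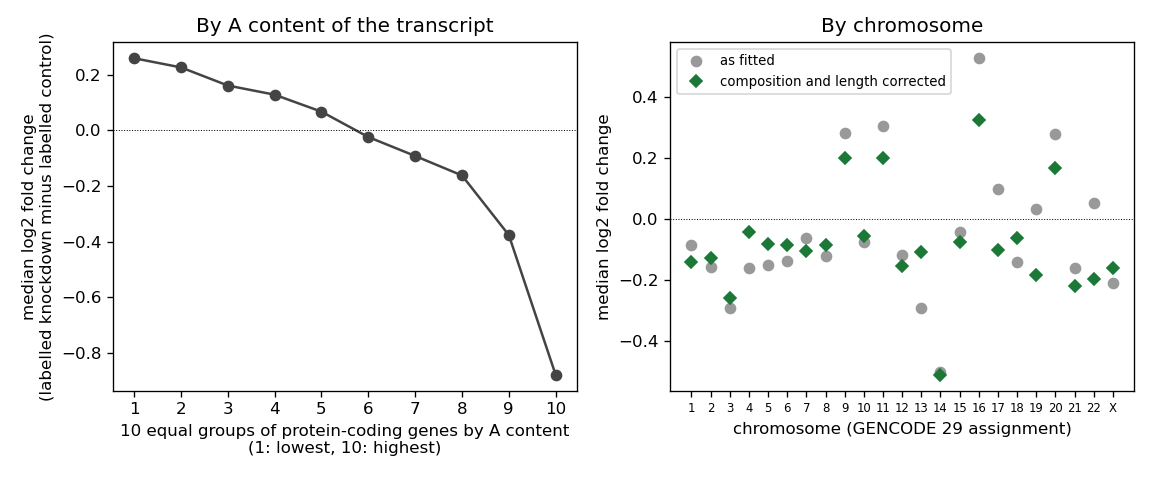
Median log2 fold change (libraries labelled knockdown minus libraries labelled control) of protein-coding genes. Left, in 10 equal groups by A content from lowest (1) to highest (10), falling from 0.26 to −0.88. Right, by chromosome, as fitted (circles) and with composition and length trends removed (diamonds), with chromosome 14 at −0.50 and −0.51 and chromosome 16 at 0.53 and 0.32.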

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

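The fits on RPKM, voom with quality weights, the GC and the composition and length corrections, and the fits without 6 chromosomes, and without chromosome 6 as well, were chosen after the data were seen. No named gene changed direction in any alternative, and of 922 values of named genes 821 kept their side of the threshold.

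The 4267 calls (1654 higher, 2613 lower in the libraries labelled knockdown) became 3020 with limma-trend on log2(RPKM + 1), with 1788 higher and 1232 lower. They became 2937 with a pseudocount of 0.5 (1705 and 1232) and 2819 with 0.1 (1603 and 1216). These fits tested 13330 genes, and 59.2% to 56.9% of calls were higher, against 38.8%; the cause of the changed split was not tested. A filter at 5 RPKM left 7700 genes and 1909 calls (790 and 1119), and a minimum log2 fold change of 1 left 1977 (555 and 1422). Voom with quality weights, which gave control replicate 2 a weight of 0.0767, called 10214 (4923 and 5291). Leaving out 1 library gave 1191 to 9063 calls, 305 to 4279 higher and 886 to 4784 lower, the highest without control replicate 2. Other filters, scalings, DESeq2 and the corrections gave 3435 to 5761. With the composition and length correction 2536 of the 4267 were called again, 5 of them in the opposite direction, and 1731 were not; with the GC correction 2490 were shared.

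TRDMT1 was higher in every fit. It passed the threshold with DESeq2 (0.64), voom (0.66), the GC correction (1.19, adjusted p = 0.0167, edgeR) and without control replicate 2 (0.79, adjusted p = 0.00249, edgeR). Leaving out 1 library gave 0.45 to 0.79. It lay below the RPKM filters, so the fits on RPKM gave no value for it other than the exact test, with p = 0.1 at each pseudocount, a test that cannot pass.

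The 8 called lists became 0 with an estimated correlation (lowest adjusted p 0.71) and 13 with fry, which compares a list with no other genes and shared 5 of the 8. Leaving out 1 library gave 7 to 11, and the fit without chromosomes 3, 9, 11, 14, 16 and 20 gave 9, in which the ATF4 targets were not called (adjusted p = 0.0736) and nuclear pore and RNA transport (0.00349) and splicing factors (0.026) were newly called. Leaving out chromosome 6 as well gave 10, with immediate early genes newly called (0.0229). The fits without chromosomes kept the trends with base composition and length. The direction of the m5C list changed in 10 of 19 alternatives and that of the migration list in 9.

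With the replicate number as a block, 2976 genes were called (1105 and 1871), of which 2852 were among the 4267, and 8 lists. Deviations of same-numbered libraries from their group mean correlated at −0.04, 0.06 and 0.00, which gives no sign that the numbers pair the libraries. With 3 libraries per group and control replicate 2 lying apart, a pairing cannot be excluded. In simulated counts a 2-fold change was recovered in 41% of the changed genes. The simulation had the same spread in both groups and no outlying library, so the share in the real libraries may differ.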

Other observations

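The Gene Ontology terms, the test of exchanged names, the verdict on the mitosis list after correction, the split of the translation term and the lists without 6 or more chromosomes were tests chosen after the results were seen. Of 77 tested genes of the term homophilic cell adhesion, 17 were higher in the libraries labelled knockdown and 0 lower, with a median of 0.41, and camera gave an adjusted p of 6.37e-05 over 739 terms, 0.000349 with composition and length trends removed and 0.848 with an estimated correlation. CDH8 (4.91 ± 0.80, adjusted p = 0.00717, edgeR), the guidance receptor ROBO2 (2.99 ± 0.27), CDH15 (1.98 ± 0.42), PCDHGC4 (1.90 ± 0.39) and PCDH1 (1.53 ± 0.18) were the highest of these, and 5 of the 17 genes, CDH3, CDH8, CDH11, CDH15 and PKD1, lie on chromosome 16.

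RNA splicing and translation were the main lower terms. Of 219 RNA splicing genes, 75 were lower and 9 higher, with a median of −0.38 (camera adjusted p = 6.37e-05, 0.0113 with trends removed, 0.848 with an estimated correlation). Of 116 genes of translational initiation, 15 were lower and 0 higher, with a median of −0.87 (adjusted p = 4.88e-05, 6.09e-05 with trends removed, 0.848 with an estimated correlation). That term holds all 77 tested genes of the cytosolic ribosomal list, which moved with control replicate 2, and of its other 39 genes 13 were lower and 0 higher, with a median of −0.56. Of 46 cholesterol metabolism genes 12 were higher and 2 lower (adjusted p = 0.00762), a call that ended with trends removed (adjusted p = 0.202) and with an estimated correlation (adjusted p = 0.848). In all, 25 terms were higher and 36 lower, and 3 and 17 of them were also called with trends removed. With an estimated correlation none was called (lowest adjusted p 0.848).

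TRDMT1 was higher in the libraries labelled knockdown. A trend with base composition and length is argued against as the whole cause, since TRDMT1 is A-rich and its log2 fold change was 0.90 ± 0.28 with the trends removed (adjusted p = 0.0637). One control library does not set the direction, since each library labelled knockdown lay above each labelled control. Leaving out a control library could therefore hardly turn it, and the lowest value was 0.45. An exchange of the group names may account for it. The samples' second names, with C for the libraries labelled knockdown and TK for those labelled control, also read the other way round. The lowest library labelled knockdown stood 1.24 times above the highest labelled control, but this is the observation itself. TRDMT1 did not pass the threshold in the main fit, though it did with DESeq2, voom, the GC correction and without control replicate 2. An exchange and a knockdown that did not lower the message cannot be told apart here. If the names were exchanged, every direction given above would turn.

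A-rich transcripts were lower in the libraries labelled knockdown. The correlation of A content with log2 fold change was −0.44 without the mitosis and replication lists. This left 13826 of 13896 protein-coding genes, so the correlation could hardly move. The listed genes alone thus do not carry it, but cell cycle genes outside the lists were not left out. A technical trend acting on every class of transcript is a possible explanation, as the correlation also held among long noncoding and antisense genes (−0.29) and pseudogenes (−0.34). For the mitosis list this explanation stays open. Its median of −0.31 lay inside the central range of 10000 random lists matched on A content and length (−0.62 to −0.13). The random lists had a median of −0.38, so the median of the mitosis list fell no further than that of a typical matched list. By the rule set beforehand this points to composition. Yet camera still called the list with trends removed (adjusted p = 0.0234 with the preset correlation, 0.734 with an estimated one), with 6 members lower and 1 higher. The ER unfolded protein response list, with its median of 0.66 against a range of −0.34 to 0.25, lay outside what its composition and length gave, and cytosolic ribosomal genes did so at −1.07 against −0.27 to 0.02, without a test of the cause.

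Genes of chromosomes 14 and 16 shifted together. Their base composition and length are argued against, since with trends removed the medians were −0.51 on chromosome 14 and 0.324 on chromosome 16, outside the central 95% of 10000 random gene sets. A different DNA copy number in the cultures of the 2 groups may be the source. All 13 runs of 50 or more neighbouring genes on chromosome 16 and all 9 on chromosome 14 lay in the direction of the chromosome, and each library labelled control went the same way. Chromosomes 5 and 15, inside their random ranges, passed as well, with 13 of 13 and 9 of 9 runs, so these counts cannot decide. Corrected run medians were 0.18 to 0.445 on chromosome 16 and −0.658 to −0.338 on chromosome 14, against −0.185 to −0.026 on chromosome 5 and −0.2 to −0.007 on chromosome 15. DNA was not analysed here, and an effect of the knockdown on these chromosomes was not tested. Without chromosomes 3, 9, 11, 14, 16 and 20, proteasome (adjusted p = 0.00582), ER unfolded protein response (0.0047) and mitosis (0.000537) were still called by camera with the preset correlation. The ATF4 targets were not (0.0736), while nuclear pore and RNA transport (0.00349) and splicing factors (0.026) were newly called. With chromosome 6 also left out, which holds TTK and a shifted segment, proteasome (0.0117), ER unfolded protein response (0.00435) and mitosis (0.000418) were still called. These fits kept the trends with base composition and length. With those trends removed over all chromosomes, nuclear pore and RNA transport (0.214) and splicing factors (0.142) were not called, and mitosis stood at 0.0234. With an estimated correlation over all chromosomes no list was called (lowest adjusted p 0.71).

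With 3 libraries in each group there are 10 splits, too few for a share under 0.05. The real split gave 4267 genes, the highest of the other splits gave 0 by edgeR with adjustment (385 at an unadjusted p under 0.05, against 6999), and 1 of the 10 splits, the real one, gave as many. For lists, the real split gave 8 and the highest other 12, and 5 of the 10 splits gave as many as the real one.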
